A study of Oryza sativa with 6 samples.

How the data were processed

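RNA was measured by sequencing in leaves of 4-week-old rice plants (Oryza sativa, japonica subspecies) of the diploid line Balilla-2x and of Balilla-4x, an artificial tetraploid made by doubling the chromosomes of that diploid. Per the labels' protocols, the plants were grown in a paddy field in Shanghai during the natural season, total RNA was taken from leaves with Trizol, and libraries were made with Illumina's TruSeq RNA kit. The labels give 3 libraries per line. They do not say whether these came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

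The authors deposited a table of raw read counts per gene for the 6 libraries, per the file headers, and a table of FPKM values for each library. Reads were aligned with HISAT2 2.1.0, per the submitters' processing notes. The counting program, the genome build, the annotation and the use of strand are not given in the sources used here. How reads shared by near-identical copies, or by overlapping genes on opposite strands, were assigned is therefore unknown, and the values of such genes are uncertain. The deposited FPKM values were checked against the counts. In 100% of nonzero values, the length in bases implied by the count, the FPKM and the library total was a whole number within 0.01, and that number was the same in every library with a count for all 30986 genes with a count. It was taken as the gene length that the authors used (138 to 13178 bases). The count and FPKM tables therefore hold the same measurement in different units, and the counts were used for every main result.

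The count table lists 55986 gene models by locus identifier, with no gene names. Of these, 55801 have an identifier of the kind used for rice loci, from which the chromosome and the order number along it were read. Another 185 belong to models that are placed on no chromosome. A table of 39387 rice genes from NCBI RefSeq (assembly ASM3414082v1) was searched for the identifiers, and 0 of them matched. The files thus do not pair the identifiers with names, and no gene is named here. For the same reason the 36 gene lists fixed before the data were examined (pathways, leaf cell types, yield, height and flowering loci) could not be filled, and their test was not run. Positions are given as chromosome and locus number, which is an order along the chromosome and not a distance in bases.

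Libraries were grouped by their labels, and the comparison made was Balilla-4x against Balilla-2x. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filterByExpr on the group, which left 20976 genes holding 99.9% of all counts, and libraries were scaled by TMM. Each gene was tested two-sided with the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the tested genes and an adjusted p threshold of 0.05. A size threshold of 2-fold was applied beside it. CPM values use the TMM-scaled library sizes. Principal components and the comparison of chromosomes and expression classes used log2 CPM with a prior count of 2. Values of single libraries are given relative to the mean of all 6 libraries, which favours neither line. The values are relative to the total RNA of each library, so a change in RNA per cell, which genome doubling could bring, is not measured.

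Each of the 12 chromosomes was tested for a shift of its genes with camera from limma 3.58.1 (preset inter-gene correlation 0.01, and again with an estimated correlation) and with an exact permutation test over the assignments of 6 libraries to groups of 3, whose smallest two-sided p is 0.1. The share of changed genes per chromosome was tested one-sided against 10000 rotations of the gene order. Runs of neighbouring changed genes were counted in windows of 10 consecutive tested genes, moved by 5 genes, with at least 5 genes changed at least 2-fold in the same direction, and were compared with 1000 shuffles of the gene order. A gene was called read in 1 line only if it had at most 2 counts in each library of a line and at least 30 in each library of the other. That definition was chosen after the counts had been seen. The design, the alternatives and the rule for named genes were fixed before the data were examined.

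The rule for named genes took those with an adjusted p under 0.05, a mean of at least 5 CPM, no overlap between the lines and a known name, by the largest fold change in each direction. Since no identifier has a name, that condition was dropped and the rule was limited to 2 genes that rose and 2 that fell. The parts of the rule that name members of gene lists and of regions were left out. Where a gene had 0 counts in all libraries of a line, its fold change was computed against a floor of 3 counts per library and is given as a lower bound. Where it had 1 count, the ratio is given with its exact Poisson interval at the 95% level. Intervals and floors cover counting error only.

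Library totals ran from 16738447 to 18106962 counts, at which 3 counts equal 0.166 to 0.179 CPM. The procedure was tested on simulated data, with counts drawn from the means and library sizes of these genes. For Balilla-4x against Balilla-2x, with 20666 genes tested, it recovered 13 of 50 genes changed 1.5-fold, 35 of 50 changed 2-fold, 43 of 50 changed 4-fold and 50 of 50 changed 8-fold. In that simulation 11 of 152 calls were unchanged genes. In separate simulations a chromosome raised 1.25-fold was called by camera (20679 genes tested), and 5 of 5 runs of 10 genes raised 8-fold were found (20659 genes tested). Genes switched off almost wholly were planted only among genes with high counts, and 20 of 20, among 20976 genes, were scored as read in 1 line only. That outcome was close to fixed by these settings. Genes were drawn independently with nothing else changed, so these simulations do not give the sensitivity for these data.

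The alternatives tried were DESeq2's size factors and library totals in place of TMM, no filter, a filter of 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, the fit without the 20 genes with the most counts, and limma on log2 of the deposited FPKM plus 1, 0.1 or 5. A test against a fold of 1.5 (glmTreat), other windows, and leaving out each library in turn were also run. Other limits for genes read in 1 line only were added after the counts had been seen.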

Results

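The transcriptome of rice leaves was compared between Balilla-2x, a diploid japonica line, and Balilla-4x, the tetraploid derived from it by chromosome doubling. Each line was represented by 3 libraries from 4-week-old field-grown plants. The title of the series names plant height, yield and yield-related genes as its subject, and the design gives 1 comparison, the tetraploid against its diploid parent. The Balilla-2x libraries held 18106962, 18036653 and 17147985 counts and the Balilla-4x libraries 16738447, 16982417 and 17078688.

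The libraries separated by line. The first principal component of log2 CPM carried 74.4% of the variance and placed all Balilla-2x libraries on one side and all Balilla-4x libraries on the other. The Pearson correlation of log2 CPM across genes was 0.971 to 0.984 within lines and 0.886 to 0.922 between lines. Genes are not independent replicates, so these values describe the libraries only. Balilla-4x replicate 1 stood apart from the other Balilla-4x libraries on the second component, which carried 8.64%. No library duplicated another, since chi-square per degree of freedom within a line was at least 8.83. More genes were read in the tetraploid, with 26333 ± 189 genes having a count against 25567 ± 7.51 (SD, n = 3 per line, exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). The 20 genes with the most counts took 8.38% ± 0.524 of the counts in Balilla-4x and 8.43% ± 0.278 in Balilla-2x (SD, n = 3 per line, exact permutation p = 0.9).

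Expression differed between the lines in both directions. Of 20976 tested genes, 5481 (26.1%) changed, 2598 of them higher and 2883 lower in Balilla-4x (edgeR quasi-likelihood test, adjusted p under 0.05). At least 2-fold changes were found for 2459 genes (11.7%), 1373 higher and 1086 lower. This count fell to 1604 in the edgeR test against a fold of 1.5, to 1585 with limma on log2 of FPKM plus 1 and to 689 with FPKM plus 5, where the direction turned, with 315 higher and 374 lower. Changes of at least 4-fold were found for 524 higher and 422 lower genes. With the 110 changed genes that had 0 counts in all libraries of a line placed at their lower bound, 131 genes were at least 16-fold higher and 107 at least 16-fold lower. Small changes were common, and 1576 of the changed genes differed by less than 1.5-fold. The lines did not overlap in 9283 tested genes (44.3%), where chance gives 10%. The count of changed genes depended on single libraries. It was 3269 without Balilla-2x replicate 3, 3029 without Balilla-4x replicate 2 and 3306 without Balilla-4x replicate 3. The direction of small changes also rested on the scaling, since 47.4% of the changed genes were higher with TMM and 57.3% with library totals.

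The most extreme genes were read in one line and had 0 or 1 counts in the other. LOC_Os12g35380 on chromosome 12 had 1704, 2109 and 1949 counts in the Balilla-4x libraries, or 111 ± 10.3 CPM (SD, n = 3), and 0 counts in each Balilla-2x library. It was at least 644-fold higher in the tetraploid (edgeR adjusted p = 7.89e-07). LOC_Os01g57250 on chromosome 1 reached 91.9 ± 12.1 CPM in Balilla-4x (SD, n = 3) with 0 counts in each Balilla-2x library, at least 532-fold higher (edgeR adjusted p = 1.47e-06). In the other direction, LOC_Os11g33394 on chromosome 11 had 4305, 3631 and 3007 counts in Balilla-2x, or 209 ± 33.2 CPM (SD, n = 3), and 1 count in all Balilla-4x libraries together. Its ratio of Balilla-2x to Balilla-4x was 10866, with an exact Poisson 95% interval of 1949.9 to 429232 (edgeR adjusted p = 1.48e-07). Of the 4 tested genes that end with LOC_Os11g33394, 1 was read in Balilla-4x only. Whether reads moved between LOC_Os11g33394 and a similar neighbour was not tested for this gene. LOC_Os02g18360 on chromosome 2 was read at 66.2 ± 9.87 CPM in Balilla-2x (SD, n = 3) and at 0 counts in each Balilla-4x library, at least 381-fold lower in the tetraploid (edgeR adjusted p = 2.91e-06). The files do not pair these identifiers with gene names.

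Genes of low abundance were more often higher than lower in the tetraploid, and abundant genes more often lower. The tested genes were divided into 5 classes of equal size by mean expression. In the lowest class (0.366 to 3.00 CPM), the median log2 fold change was 0.34, and 570 genes were at least 2-fold higher against 254 lower. In the next class (up to 10.4 CPM) the median was 0.16, with 425 higher and 288 lower. The middle class had a median of 0.01. In the next class (25.3 to 58.4 CPM) the median was -0.07, with 114 higher and 164 lower, and in the highest class it was -0.11, with 101 higher and 175 lower. In the lowest class the library medians, taken relative to the mean of all 6 libraries, were 0.19 ± 0.07 in Balilla-4x and -0.12 ± 0.03 in Balilla-2x (log2, SD, n = 3 per line, exact permutation p = 0.1, the smallest possible). In the highest class they were -0.05 ± 0.01 and 0.06 ± 0.0036 (log2, SD, n = 3 per line, exact permutation p = 0.1). In the middle class the exact permutation p was 0.2. Benjamini-Hochberg adjustment over the 5 classes gave 0.125 for the lowest and the highest class (exact permutation test), a value that 3 libraries against 3 cannot bring under 0.05. With library totals in place of TMM, the medians from the lowest to the highest class were 0.40, 0.22, 0.07, -0.01 and -0.05, in the same order. The counts at least 2-fold higher and lower were then 624 and 236 in the lowest class and 109 and 153 in the highest.

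**Figure D1:**
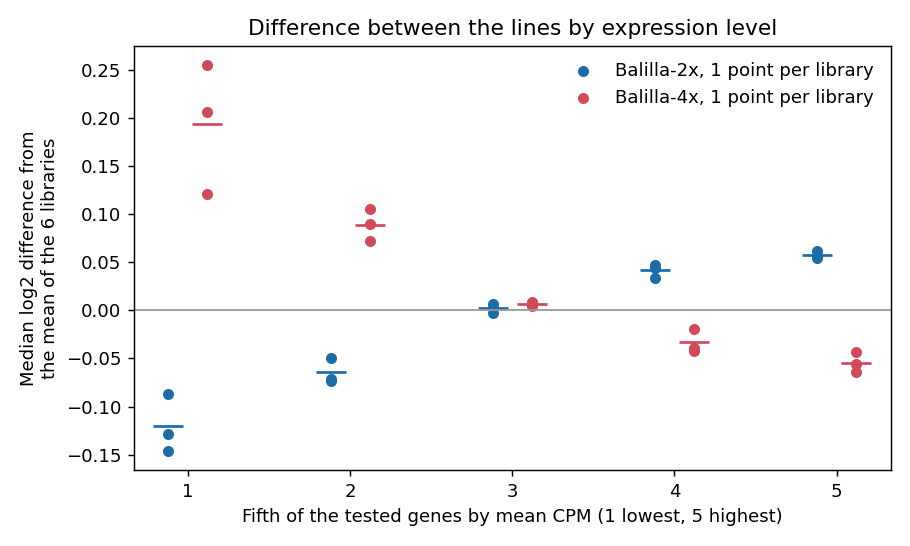
Median log2 difference of each library from the mean of the 6 libraries (vertical axis) in 5 classes of tested genes from lowest to highest mean CPM (horizontal axis), with 1 point per library and a bar at the mean of each line. The Balilla-4x libraries lie above all Balilla-2x libraries in the lowest class, with means of 0.19 and -0.12, and below them in the highest class, with means of -0.05 and 0.06.

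Chromosomes as a whole differed little between the lines. Camera called 0 of 12, and the lowest unadjusted p was 0.401, so 0 were under 0.05. With an estimated inter-gene correlation it again called 0 (limma camera, adjusted p = 0.931 for each chromosome). The median difference between the lines over a chromosome's genes, relative to the other chromosomes, lay between -0.04 (chromosome 4) and 0.03 (chromosome 10) on the log2 scale. The exact permutation test gave its smallest possible p, 0.1, for chromosomes 4, 10 and 11, whose shifts were -0.04, 0.03 and 0.01, and 0.4 for each of them after Benjamini-Hochberg adjustment over the 12 chromosomes. The medians of single libraries did not overlap between the lines on chromosomes 4 and 10, but they did on chromosome 11. They did not overlap on chromosomes 1 and 5 either, where the exact permutation p was 0.5 and 0.3. For scale, as a difference between the lines a ratio of 5 copies to 4 is 0.32 and a ratio of 3 to 4 is -0.42. In single libraries, relative to the mean of all 6, the median lay between -0.02 and 0.03 in Balilla-2x and between -0.03 and 0.10 in Balilla-4x. That mean includes the library itself, so a copy change would appear smaller there than the ratios above. The value of 0.10 was that of chromosome 2 in Balilla-4x replicate 2, and the next highest in Balilla-4x was 0.03.

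Chromosome 11 held the largest share of genes changed at least 2-fold. There 243 of 1214 tested genes (20.02%, exact 95% binomial interval 17.8% to 22.4%) changed, 116 higher and 127 lower, while the share on the other chromosomes was 9.71% to 12.4%. The interval takes genes as independent, but changed genes lay in clusters, so it is too narrow. Against 10000 rotations of the gene order the one-sided p of chromosome 11 was 0.0112 in this permutation test. Adjusted over the 12 chromosomes by Benjamini-Hochberg it was 0.134 (permutation test), which does not pass the threshold. Rotations by a few genes leave most genes of the chromosome in place and return nearly the same share, which keeps this p from becoming very small. The test therefore cannot decide whether chance placement gave the excess.

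**Figure D2:**
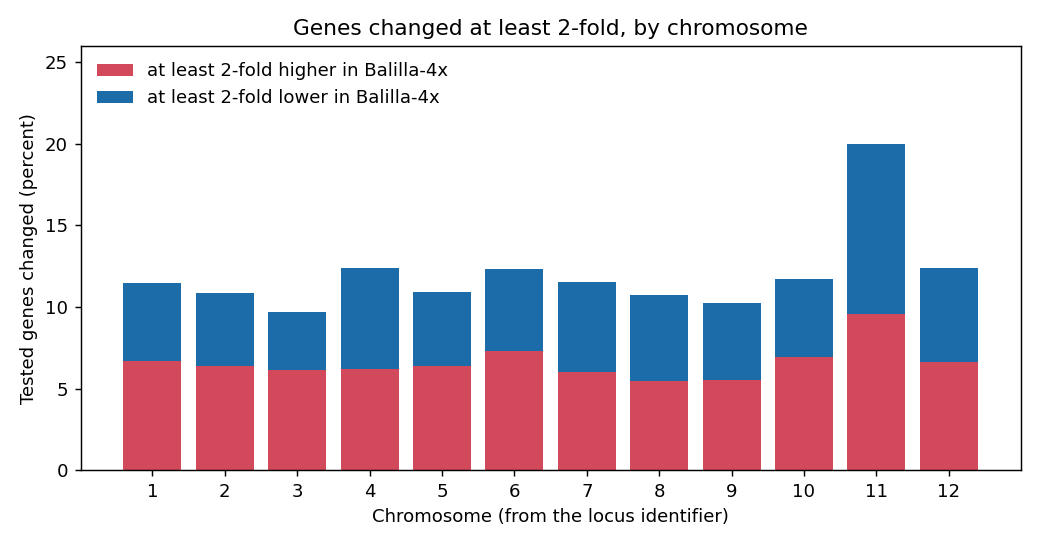
Percentage of the tested genes of each chromosome (horizontal axis) that were at least 2-fold higher or at least 2-fold lower in Balilla-4x, stacked (vertical axis). Chromosome 11 reaches 20.02% and the other chromosomes lie between 9.71% and 12.4%.

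Changed genes lay next to each other more often than chance placement gives. At least 5 of 10 consecutive tested genes changed at least 2-fold in the same direction in 27 of 4174 windows, while 1000 shuffles of the gene order gave a mean of 1.26 and at most 6 (permutation test, one-sided p = 0.001, the smallest these shuffles can give). Overlapping windows merged into 16 regions, 11 with at least 5 genes higher and 5 with at least 5 genes lower in Balilla-4x, which held 115 genes changed in the region's direction. The longest lay on chromosome 6 between locus numbers 38110 and 38870. Of its 27 tested genes 21 were higher in the tetraploid and 0 lower, and the remaining genes did not pass both thresholds. Together they summed to 5774 ± 1236 CPM in Balilla-4x and 259 ± 13.999 CPM in Balilla-2x (SD, n = 3 per line), and the highest gene reached 43659 counts in a library. Its median log2 fold change was 8.05 as fitted and 5.55 with genes at 0 counts placed at their bound.

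The other regions with at least 5 higher genes were smaller, and the count of higher genes did not always go with a higher sum. On chromosome 2, locus numbers 40190 to 40340, 5 of 7 tested genes were higher and 2 lower, and the sums were 62.8 ± 5.19 CPM in Balilla-2x and 1213 ± 92.8 CPM in Balilla-4x (SD, n = 3 per line). On chromosome 12, locus numbers 2310 to 2385, 6 of 8 were higher, with sums of 258 ± 47.0 CPM in Balilla-2x and 1309.5 ± 353 CPM in Balilla-4x (SD, n = 3 per line). On chromosome 9, locus numbers 19280 to 19350, all 5 tested genes were higher, with 32.5 ± 4.14 CPM in Balilla-2x and 424 ± 172 CPM in Balilla-4x (SD, n = 3 per line). On chromosome 1, locus numbers 57250 to 57340, 5 of 6 were higher, with 26.1 ± 4.07 CPM in Balilla-2x and 185 ± 18.9 CPM in Balilla-4x (SD, n = 3 per line). By contrast, on chromosome 2, locus numbers 43170 to 43370, 5 of 9 were higher and 2 lower, and the sums were 257 ± 10.1 CPM in Balilla-2x and 239 ± 25.5 CPM in Balilla-4x (SD, n = 3 per line). On chromosome 4, locus numbers 14220 to 14730, 5 of 10 were higher and the sums were 250.9 ± 8.97 CPM in Balilla-2x and 269 ± 9.84 CPM in Balilla-4x (SD, n = 3 per line).

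Regions with at least 5 genes lower in Balilla-4x lay on chromosomes 7, 10, 11 and 12. On chromosome 11, locus numbers 40760 to 41100, 9 of 11 tested genes were lower, and the sum was 404 ± 44.6 CPM in Balilla-2x and 15.1 ± 1.59 CPM in Balilla-4x (SD, n = 3 per line). On chromosome 12, locus numbers 8240 to 8564, 5 of 7 were lower, with 475 ± 70.0 CPM in Balilla-2x and 102 ± 6.77 CPM in Balilla-4x (SD, n = 3 per line). Chromosome 11 also held a region of lower genes beside a region of higher ones. Between locus numbers 11770 and 11990, 9 of 12 genes were lower in the tetraploid and 0 higher, with sums of 1254 ± 82.4 CPM in Balilla-2x and 427 ± 103 CPM in Balilla-4x (SD, n = 3 per line). Between 12010 and 12590, 9 of 14 were higher and 1 lower, with sums of 295 ± 21.99 CPM in Balilla-2x and 415 ± 106 CPM in Balilla-4x (SD, n = 3 per line).

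**Figure D3:**
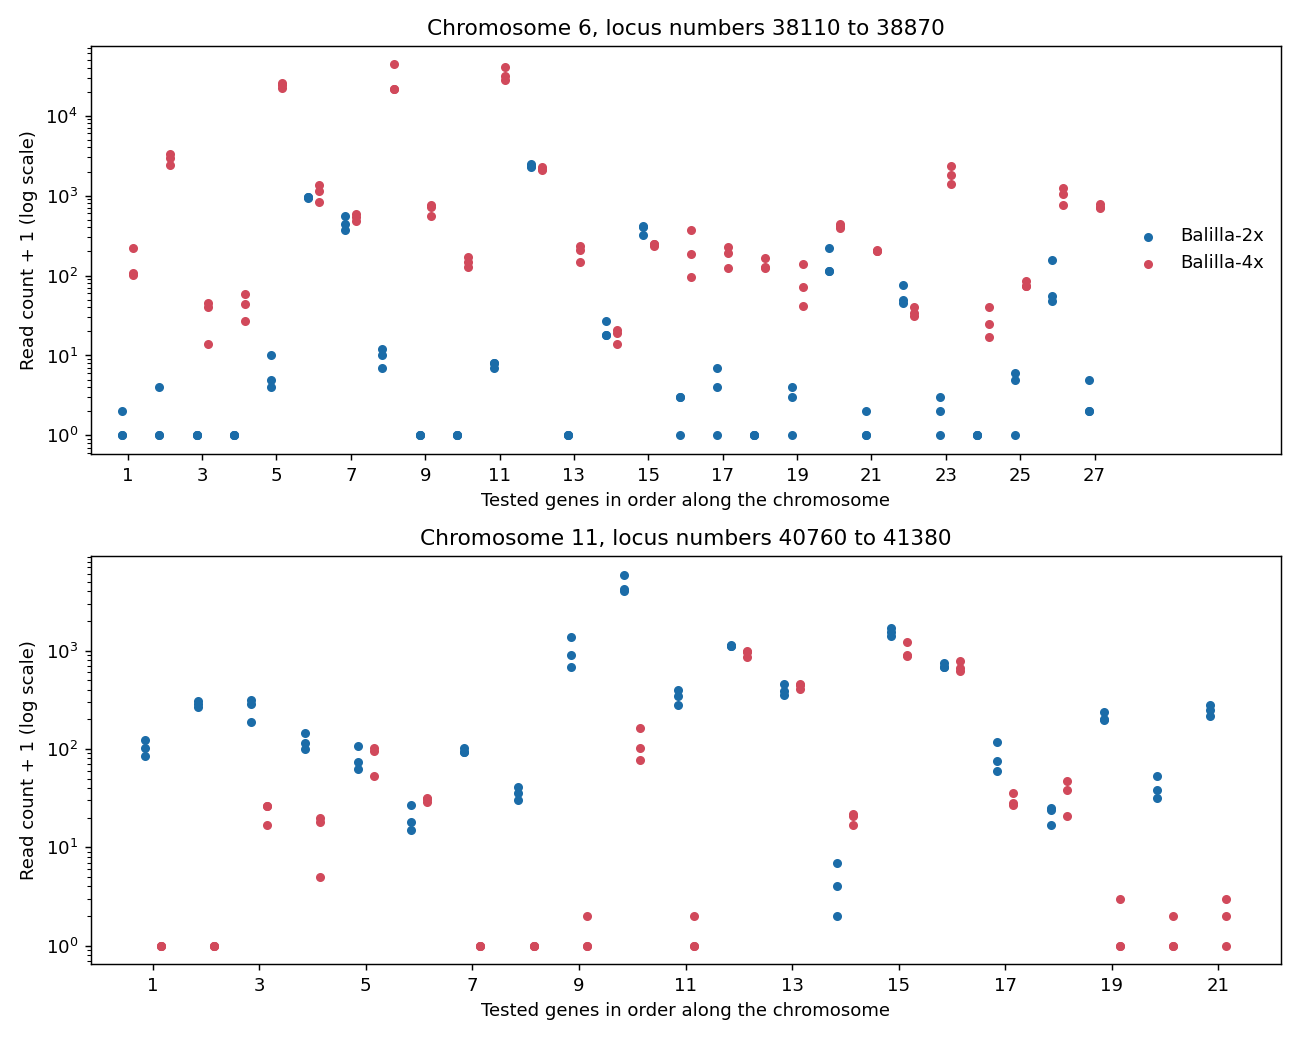
Read count plus 1 (vertical axis, log scale) of each tested gene in order along the chromosome (horizontal axis), with 1 point per library (Balilla-2x blue, Balilla-4x red), for a region of chromosome 6 (upper panel) and of chromosome 11 (lower panel). In the chromosome 6 region 21 of 27 genes were higher in Balilla-4x, and in the first 11 genes of the chromosome 11 region 9 were lower. Of all 21 genes of the chromosome 11 region, 8 were read in Balilla-2x only, and 6 of the other 13 changed at least 2-fold. Both regions also held genes that did not pass both thresholds.

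In 102 genes reads were found in 1 line only, by the limits of at most 2 counts in each library of a line and at least 30 in each library of the other. These limits were chosen after the counts had been seen. Balilla-4x alone read 53 of them, at a median of 11.2 CPM, and Balilla-2x alone read 49, at a median of 8.16 CPM. In 59 of the 102 genes the silent line had 0 counts in all 3 libraries. Chromosome 11 held 39 of them, 12 read in Balilla-4x only and 27 in Balilla-2x only. They were clustered, with 38 successive pairs lying within 10 tested genes of each other, against a mean of 4.69 and a highest value of 13 in 1000 shuffles. With at least 100 counts asked of the reading line, 57 genes were left.

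**Figure D4:**
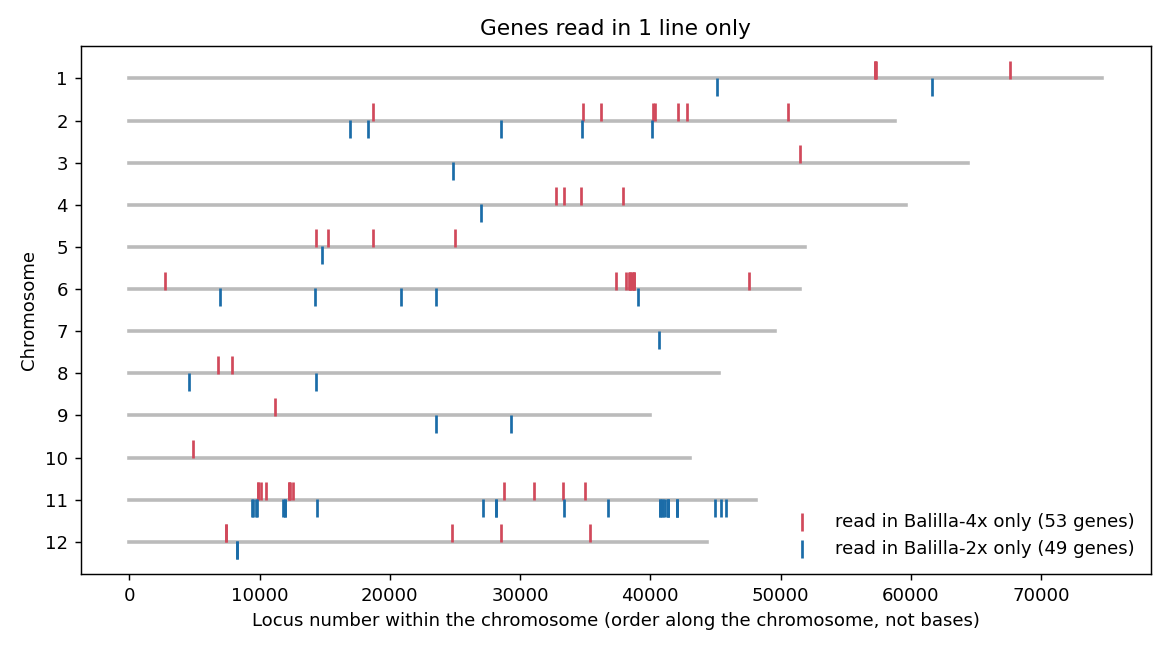
Position of the 102 genes read in 1 line only, by locus number (horizontal axis, order along the chromosome and not bases) on each of the 12 chromosomes (vertical axis), with a mark for each gene above the line if read in Balilla-4x only and below it if read in Balilla-2x only. Chromosome 11 carries 39 of the marks, and chromosome 6 a cluster of genes read in Balilla-4x only near locus number 38110.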

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

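Most counts of changed genes stayed within 1.5 times the reported ones. Over scalings, filters, tests and FPKM in place of counts, the number of changed genes ran from 5139 (limma on log2 of FPKM plus 5) to 6067 (DESeq2), against 5481. The number changed at least 2-fold, 2459, moved further with limma on log2 of FPKM plus 1 (1585) and plus 5 (689), where the added value itself shrinks the folds of low genes, and in the test against a fold of 1.5 (1604), which asks for more than a fitted 2-fold. Of these genes 55.8% were higher in Balilla-4x as reported, 60.6% with library totals, 60.1%, 50.4% and 45.7% with FPKM plus 0.1, 1 and 5, and 52.3% to 56.6% with a library left out. Among all changed genes the share that was higher turned from 47.4% to 57.3% with library totals and to 56.9% with limma on log2 of FPKM plus 1. Windows with changed genes in either direction numbered 61 (shuffles: mean 13.8, at most 29) against 27. Of the limits for genes read in 1 line only, added after the counts had been seen, the demand for 100 counts gave 57 genes, and the others 115 and 104, against 102. Leaving out each library in turn gave 3029 (without Balilla-4x replicate 2) to 6600 (without Balilla-4x replicate 1) changed genes, 1814 to 2943 changed at least 2-fold, 19 to 40 windows, and 108 to 119 genes read in 1 line only. Without Balilla-2x replicate 3 the changed genes were 3269 and without Balilla-4x replicate 3 they were 3306. Fewer libraries leave fewer degrees of freedom, but leaving out Balilla-4x replicate 1 acted the other way. Its log2 CPM correlated with Balilla-4x replicates 2 and 3 at 0.972 and 0.971, against 0.984 between those. Whether this accounts for the higher count was not tested. No chromosome was called under any alternative run. The 4 named genes kept their direction and call in each of the 14 alternatives run for them, or 56 results (adjusted p from 4.75e-27 in DESeq2 to 0.000111 in edgeR with the replicate block). They were not checked with FPKM or in the test against a fold of 1.5. Since they were picked for the largest folds without overlap, keeping the call was close to assured. The replicate numbers do not pair the libraries, since deviations of same-numbered libraries from their line's mean correlated at 0.002, -0.02 and -0.04 across genes. With the number as a block, 4617 genes changed, 2219 at least 2-fold, and 0 chromosomes were called. The test of the gene lists and all its alternatives were not run, since no list could be filled. On simulated data 13 of 50 genes changed 1.5-fold were recovered. The simulation gave 152 calls against 5481 here, so its adjusted threshold was stricter, and it did not vary the depth. That share is therefore not the sensitivity of this comparison.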

Other observations

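The definition of genes read in 1 line only and the tests of opposite neighbours, of mixed segments and of other splits for these genes were chosen after the results had been seen. So were the test of a background of reads, the argument against noise of low counts and the use of a counting interval for chromosome 11.

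Genes read in 1 line only formed 10 segments with at least 3 such genes, which together held 42 of the 102. The largest were on chromosome 6, with 8 genes read in Balilla-4x only among 23 tested genes between locus numbers 38110 and 38764, and on chromosome 11, with 8 read in Balilla-2x only among 21 between 40760 and 41380. Of the other tested genes inside them, 9 of 15 and 6 of 13 changed at least 2-fold. On chromosome 5, between 14330 and 15220, 0 of 13 other genes did. Another 48 genes stood alone. When a library was left out, 85.7% to 94.4% of the genes picked from the other libraries read in it as in its own line.

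Among genes too low to be tested, the tetraploid libraries also held more reads. The 35010 untested genes took 0.155% ± 0.0101 of the counts in Balilla-4x and 0.115% ± 0.0144 in Balilla-2x (SD, n = 3 per line, exact permutation p = 0.1, the smallest possible).

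The genes read in 1 line only may mark stretches of DNA that differ between the lines, and this was tested on their neighbours. The 1293 other genes within 10 positions had a median absolute log2 fold change of 0.365, above the median of 0.308 in 10000 rotations of the gene order (permutation p = 0.001), and when matched on 20 classes of mean CPM their median percentile was 56.1 against 49.8 (permutation p = 0.0005). Reads moved between neighbouring copies that are each read in 1 line only are argued against as the general cause for the 54 genes with another such gene within 10 tested genes. Such moved reads would need a gene of the opposite kind beside each of these, and 25.9% of them had one. In 1000 shuffles of the directions the mean was 75.4% and the lowest value 40.7%. The shuffles took genes as independent, but these genes lie in segments, the largest with 8 genes each of 1 kind only. The shuffled values are therefore no level of chance, and the argument rests on the 25.9% alone. For the 14 genes that do have an opposite neighbour, moved reads stay open. For the 48 genes that stood alone, and for copies that both lines read or that lie farther away, this was not tested. Switching of whole segments in the tetraploid stays open, since 30% of the 10 segments held genes of both kinds, a share between what switching and its absence would give, and the neighbours' changes go with it too. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many such genes, the real one with 102 against at most 0 in the others. Every other split mixes both lines in each group, where a gene read in 1 line only cannot count. Its 0 is therefore no level of chance, and 10 splits are too few for a share under 0.05.

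More genes were at least 2-fold higher than lower in Balilla-4x, and the excess came from genes of low abundance, since among genes with a mean of at least 5 CPM 45.9% were higher (exact 95% interval 43.2% to 48.6%). The choice among the 4 scalings tried is argued against as its cause, because the lowest share was 55.8% (exact 95% interval 53.8% to 57.8%, which takes genes as independent). That lowest share was the one with TMM. The other scalings placed Balilla-4x higher, with a median log2 fold change of 0.015 to 0.070 against 0.011 with TMM. A scaling that places Balilla-4x lower was not tried, so scaling in general is not excluded. Gene length is argued against too, because 54.5% (52.5% to 56.5%) were higher after its trend was removed. With a library left out the share ran from 52.3% (without Balilla-2x replicate 2) to 56.6%. Only without Balilla-2x replicate 1 was it above the reported 55.8%, and with the replicate block it was 52.7%. With limma on log2 of FPKM the share went with the value added, which shrinks the folds of low genes. It was 60.1% with 0.1, 50.4% with 1 and 45.7% with 5, where the direction turned. A uniform background of reads in the tetraploid libraries, such as DNA carried into them, would have to reach most genes, at about 4.91 counts per library in the lowest class. Of the untested genes 76.3% had 0 counts in all Balilla-4x libraries. However, only 30986 of the 55986 gene models had a count in any library. Models without a count in either line may be unable to take reads, so this test cannot decide on a background. Noise of low counts alone is argued against for the lowest class and the next, since noise would favour neither line. Relative to the mean of all libraries, the log2 medians of the lowest class were 0.12 to 0.25 in the Balilla-4x libraries. In the Balilla-2x libraries they were -0.15 to -0.09. In the next class they were 0.07 to 0.11 in Balilla-4x and -0.07 to -0.05 in Balilla-2x. Whether noise adds to the excess was not tested. The argument against noise rests on 3 libraries per line (exact permutation p = 0.1 in both classes, the smallest possible). It does not speak to differences other than noise between the libraries of the lines. A different mix of cells or stage in the tetraploid leaves and an effect of ploidy itself stay open and were not tested.

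The high share of changed genes on chromosome 11 may come in part from the segments around genes read in 1 line only. Outside 10 positions of such genes it fell from 20.02% to 13.9% (117 of 844, exact 95% interval 11.6% to 16.4%, which takes genes as independent), while the other chromosomes lay between 9.68% and 11.9%. The bound set beforehand against the segments as the whole cause, 1 SD (0.743 points) above the highest other chromosome, was passed, but it made no allowance for counting error, and since the interval of the 844 genes reaches into the range of the others, whether the segments account for the whole excess cannot be told apart from a wider difference on this chromosome. The expression level of its genes is argued against, because the share was 18.8% when standardized over 10 classes of mean CPM, against 10.3% to 12.4% elsewhere. Ploidy as its cause stays open and was not tested.

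For the counts of changed genes (5481), of genes changed at least 2-fold (2459) and of windows with runs (27), 1 of the 10 splits gave a result as large, the real one, and the highest of the others was 0 each time. Every other split mixes both lines in each group, so the difference between the lines widens the spread within its groups. These values of 0 are therefore no level of chance, and the splits are too few for a share under 0.05.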
